A study of Mus musculus with 6 samples.

How the data were processed

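Messenger RNA of 6 mouse hearts was sequenced, 3 from vehicle-treated and 3 from trametinib-treated females. Libraries came from a stranded mRNA kit and shared a single-end NextSeq run, per the labels' protocols. RNA was isolated with either of 2 kits, and which kit served which heart, and the days of collection and library preparation, are not given in the sources used here. Picard 1.64, SAMtools, RSEM and DESeq2 and the build mm9 are named without role or order, per the submitters' processing notes. The aligner and annotation are not given in the sources used here.

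The deposited values are a normalized signal per gene: estimated counts that the authors had divided by 1 factor per library, as the values themselves show. The upper quartile of the values above 0 lay between 997.851 and 999.464 in every library and the totals between 21656431 and 22330993. Low values were mostly multiples of a step of 1.357 to 1.541 in vehicle and 0.892 to 0.940 in trametinib libraries; 87.5% to 89.4% of values below 50 steps lay within 0.05 of a whole multiple. That share was too low to treat the values as counts, so no count model was used in the main test. Among the alternatives, voom and thinning treated values divided by their step as estimated reads. Dividing each total by its step estimated the depth at 14304826 to 16046500 reads for vehicle and 23033856 to 24691501 for trametinib. Depth therefore went with treatment, and the 10 genes with the highest values held 12.4% to 12.9% of each total. A further column of per-sample values (1 in all) matched no labelled sample and was not used, and neither were the means and ratios the authors had formed.

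The table held 21705 rows. Symbols that had become numbers in 26 rows were restored from their Entrez identifiers. Identifiers of 21562 rows matched the reference gene table, which served for names only. Genes with a mean value of at least 10 were tested (13581) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and no robust option, on log2(value + 1). Adjustment was by Benjamini-Hochberg and the threshold an adjusted p of 0.05. This was the planned fallback for a table without counts. The intended count test was not run. Sets were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with the directional fry test, for the 44 of 47 lists with at least 4 tested members. Mitochondrially encoded genes had 0 rows in the table, and B cell markers and lung and thymus markers had 2 and 1 tested members. The lists, the tests and the rule for naming genes were fixed before the data were examined, although the series title names mitochondria and innate immunity. The rule named the 10 largest changes in each direction among genes past the threshold with non-overlapping arms and a mean of at least 30, up to 5 members with the smallest p in each list, the 5 genes with the smallest p, and a fixed set of genes of interest that held Map2k1, Map2k2, Mapk3, Dusp6, Spry4, Etv4, Etv5, Ppargc1a, Nppa, Nppb, Myh6 and Myh7. Some genes that the rule names are not reported here. Myl7 was added after its values were seen.

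Mean transcript length and GC content per gene came from GENCODE M21 transcripts and covered 99.2% of tested genes and 100% of the respiratory chain, ribosomal protein and interferon lists. The correction subtracted, in each library, a lowess curve (span 0.3) on length and then on GC content. It cannot separate a length artifact from a biological change that follows length. Matched random lists were drawn 10000 times from the 50 nearest genes in length, GC content and mean value.

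The code was tested on simulated libraries of the same depths with 200 genes changed. Among 13550 genes tested, 70% of the 2-fold and 90% of the 4-fold changes were recovered, each with the right sign. Of 171 calls, 11 were wrong, and 0 genes were called with nothing changed. In these runs few genes changed, genes varied independently and no length trend went with the arm. The data differ in all of these, so the rates need not hold there. Alternatives covered normalization, filters, thresholds, pseudocounts, each heart left out, the replicate number as a block, haemoglobin genes removed, median-of-ratios scaling, length and GC correction, voom on estimated reads and thinning to the shallowest library. The last 4 were chosen after seeing the data.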

Results

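Whole-heart messenger RNA was measured in wild-type FVB female mice aged 12 to 16 weeks that received vehicle or trametinib, an inhibitor of the kinases MEK1 and MEK2, at 3 mg/kg once daily for 14 days. There were 3 hearts in each arm, each from a separate animal, so the p-values reflect the spread between animals. The values were normalized counts per gene, scaled by the authors to a common upper quartile, and summed to between 21656431 and 22330993 per heart. The smallest step between low values gave an estimated depth of 14304826 to 16046500 reads in the vehicle hearts and 23033856 to 24691501 in the trametinib hearts, so the trametinib values rest on more reads.

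The largest changes with trametinib included interferon-inducible transcripts such as Igtp, which were higher, and the natriuretic peptide Nppa and skeletal actin Acta1, which were lower. Of 13581 genes tested with limma, 2939 were higher and 3098 lower at an adjusted p below 0.05, and 388 and 417 of these changed by a log2 fold change of 1 or more. The direction with more genes depended on the scaling and on the hearts used. With voom 2516 were higher and 3587 lower, and with median-of-ratios scaling 3158 and 2918. A length and GC correction gave 2418 higher and 2081 lower, and leaving out vehicle replicate 3 gave 2804 and 2584. The first principal component held 57.2% of the variance and separated the arms, with trametinib replicate 3 apart from the others of its arm (56.9 against 27.4 and 30.6). Over the 500 most variable genes it stood at 50.7 against 6.94 and 16.0, a wider gap than that between trametinib replicate 1 and vehicle replicate 3 (-9.69). Correlations were 0.969 to 0.988 within an arm and 0.927 to 0.963 between arms. The 5 genes with the smallest p were all higher: Zbtb20, a zinc-finger repressor (log2 fold change 1.66 ± 0.07, SE), Ppp1r3a, a glycogen-targeting phosphatase subunit (4939 ± 311 and 13940 ± 790 normalized counts, SD, n = 3), AI314180 (1.04 ± 0.05), Ube2l6, the conjugating enzyme for ISG15 (1.71 ± 0.08), and Med13, a Mediator subunit (1.19 ± 0.06), each with adjusted p = 0.000176. The 3 trametinib values lay wholly above or below the 3 vehicle values for 7667 genes, or 56.5%, where chance gives 10%. Fold changes are on the log2(value + 1) scale, which understates the change of low genes.

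Fold change followed transcript length across genes, with a Spearman rho of 0.47, where genes are not independent replicates. In the shortest 2695 genes, up to 1310 nt, 1521 were lower and 124 higher, and in the longest 2694 genes 144 were lower and 1257 higher. The trend appeared in each of the 9 vehicle and trametinib pairs, with rho from 0.38 to 0.46, whereas within an arm it ran from -0.17 to 0.21. Transcripts of respiratory chain subunits and ribosomal proteins are short, and their values below are given with the size that remained after correction for length and GC content.

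**Figure D1:**
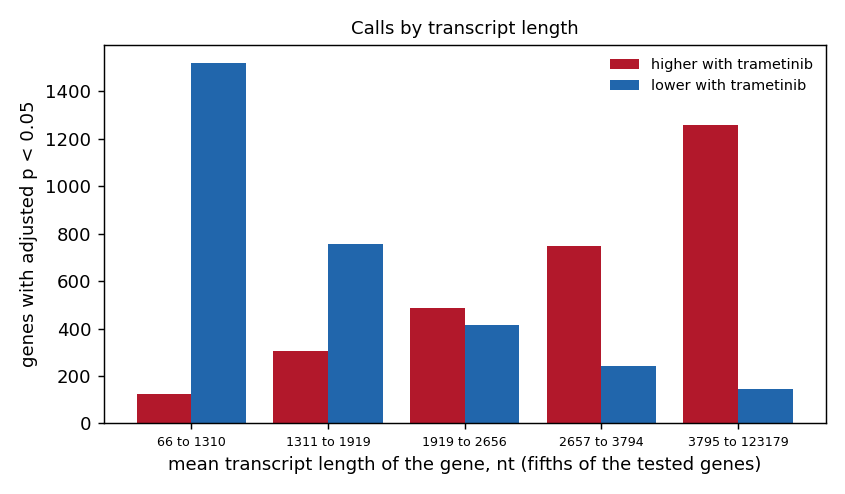
Number of genes with an adjusted p below 0.05 (vertical axis) in 5 equal bins of the tested genes by mean transcript length in nt (horizontal axis), red for higher and blue for lower with trametinib. Lower genes fall from 1521 in the shortest bin to 144 in the longest, and higher genes climb from 124 to 1257.

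The comparison addressed first the pathway that the drug blocks. Transcripts of several ERK-induced genes were lower. The ETS factor Etv5 fell from 351 ± 33.1 to 110 ± 10.6 normalized counts (SD, n = 3; log2 fold change -1.66 ± 0.12, SE; adjusted p = 0.000245), and Etv4, at a far lower level, from 17.9 ± 7.63 to 2.12 ± 0.48 (adjusted p = 0.00835). Phlda1 (-1.83 ± 0.31) and the feedback inhibitors Spry1 (-0.97 ± 0.13) and Spred2 (-0.49 ± 0.09) were lower as well, and the ephrin receptor Epha4 was higher (0.85 ± 0.09). Of the 23 tested ERK target and feedback genes, 9 were lower, 1 higher and 13 did not pass, with the same counts when adjusted over the list alone. With a heart left out, the number lower ran from 5 (without vehicle replicate 3) to 11. As a set they missed the threshold (camera adjusted p = 0.0714; adjusted p = 0.659 with an estimated correlation). The feedback phosphatase Dusp6 measured 516 ± 138 in vehicle and 343 ± 111 in trametinib hearts (adjusted p = 0.102), and Spry4 314 ± 17.0 and 276 ± 129 (adjusted p = 0.458). Without trametinib replicate 3 both passed, Dusp6 at an adjusted p = 0.0354 and Spry4 at 0.0322, and with the replicate number as a block Dusp6 passed (adjusted p = 0.00561).

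The genes for MEK1 and MEK2, the drug's targets, showed no change past the threshold in the main test: Map2k1 had a log2 fold change of -0.13 ± 0.06 (adjusted p = 0.131) and Map2k2 of -0.04 ± 0.06 (adjusted p = 0.543). Map2k1 passed after thinning (-0.21, adjusted p = 0.04) and with voom (-0.18, adjusted p = 0.0483). Mapk3, which encodes ERK1, was slightly lower (-0.19 ± 0.06; adjusted p = 0.0337), a call lost without any of 5 of the 6 hearts, with adjusted p up to 0.118. The length and GC correction reversed the signs of Map2k2 (0.22, adjusted p = 0.0131) and Mapk3 (0.10, adjusted p = 0.186). Among the 18 MAPK pathway components, 7 were higher, including the exchange factors Sos1 (0.76 ± 0.12; 0.28 after the correction, adjusted p = 0.112) and Sos2 (0.60 ± 0.07) and the scaffold Ksr1 (0.82 ± 0.12), and 2 were lower, including Araf (-0.33 ± 0.06). The list as a set did not pass (camera adjusted p = 0.152).

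**Figure D2:**
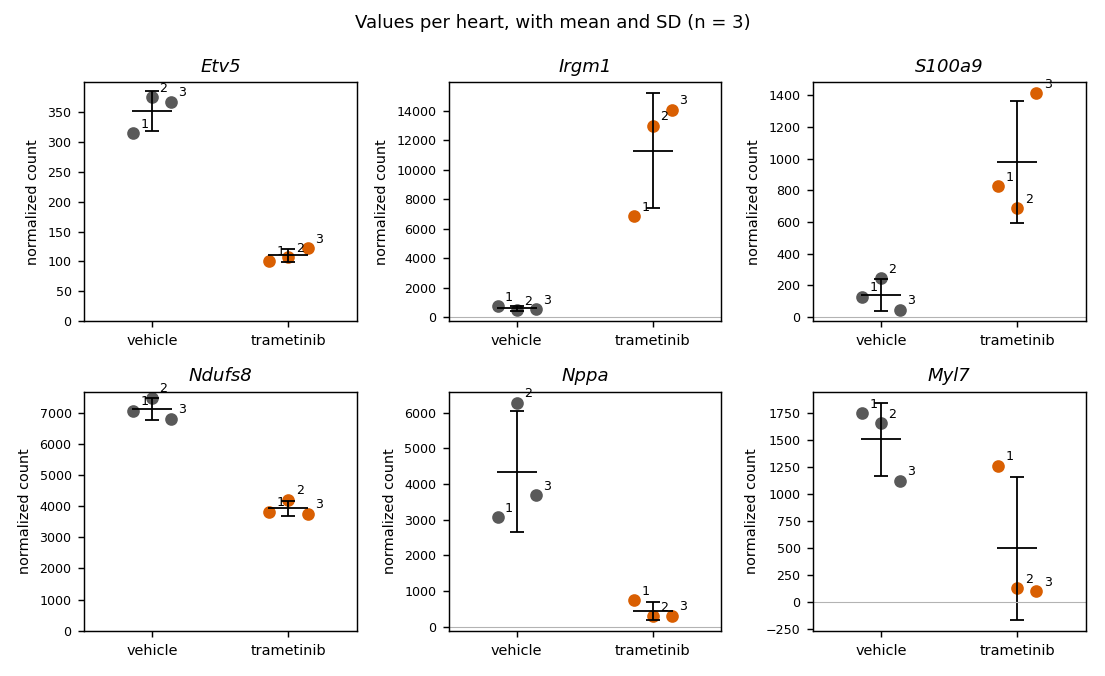
Normalized counts (vertical axes) of 6 genes in each heart, grey for vehicle and orange for trametinib, numbered by replicate, with horizontal lines at the mean and bars of 1 SD (n = 3). Etv5, Ndufs8 and Nppa are lower in every trametinib heart and Irgm1 and S100a9 higher, whereas Myl7 in trametinib replicate 1, at 1263, lies inside the vehicle range of 1122 to 1748.

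Mitochondrial transcripts, the subject of the series title, were lower across the nuclear-encoded respiratory chain. All 78 tested subunits of complexes I to V were lower, with a median log2 fold change of -0.78. Complex I had 36 of 36 members lower, among them Ndufs8 (7114 ± 338 and 3925 ± 246; log2 fold change -0.86 ± 0.07) and Ndufa3 (-1.21 ± 0.10). Complex II had 4 of 4 (Sdhc -0.75 ± 0.06; Sdha -0.19 ± 0.06, a call lost without any of 4 of the 6 hearts, with adjusted p up to 0.101), and complex III 9 of 9 (Cyc1 -0.74 ± 0.05, Uqcrc1 -0.68 ± 0.06). Complex IV had 13 of 13, with the heart and muscle isoforms Cox8b at -1.34 ± 0.13 and Cox7a1 at -1.17 ± 0.11, and complex V 16 of 16, with Atp5g3 at -1.11 ± 0.07 and Atp5e at -1.48 ± 0.12. Camera adjusted p-values were 9.53e-17 for complex I, 0.00898 for II, 4.33e-06 for III, 1.67e-07 for IV and 8.06e-09 for V, with adjusted p = 0.556 with an estimated correlation for each. Counts adjusted over each list alone were the same. After the length and GC correction, the median of the subunits was -0.22 and 40 of the 78 were lower and 2 higher (1 each of complexes I and IV). Uqcrc1 and Sdha then no longer passed, at -0.09 (adjusted p = 0.225) and -0.11 (adjusted p = 0.236).

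Enzymes of oxidative metabolism were also lower. Of 25 TCA cycle genes, 19 were lower and 1 higher, with Mdh2 at -0.69 ± 0.05 and the pyruvate dehydrogenase subunit Pdhb at -0.75 ± 0.06 (camera adjusted p = 1.61e-06; adjusted p = 0.556 with an estimated correlation). Of 27 fatty acid oxidation genes, 18 were lower and 1 higher (19 and 1 adjusted over the list alone), with Echs1 at -0.86 ± 0.07 and Acads at -0.84 ± 0.07 (camera adjusted p = 6.20e-06; adjusted p = 0.582 with an estimated correlation). After the length and GC correction, these medians went from -0.35 to -0.31 for the TCA cycle and from -0.56 to -0.36 for fatty acid oxidation. Ppara, a nuclear receptor for lipid oxidation genes, was higher (1.09 ± 0.10; adjusted p = 0.000296), as was Esrrg (0.50 ± 0.07), and Tfam, the mitochondrial DNA packaging factor, was lower (-0.35 ± 0.08). Ppargc1a, a coactivator of mitochondrial biogenesis, measured 6116 ± 2203 and 8303 ± 2426 (adjusted p = 0.275). It passed with the replicate number as a block (adjusted p = 0.00635), although the labels give only a shared number. The biogenesis list had 8 genes higher and 2 lower of 23 (camera adjusted p = 0.485; its median of -0.04 and mean of 0.07 differed in sign).

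Of 52 cytosolic ribosomal protein transcripts, 50 were lower, with a median of -0.69 (Rpl24 -1.13 ± 0.11, Rps9 -0.81 ± 0.08; camera adjusted p = 1.98e-16; adjusted p = 0.556 with an estimated correlation). After the length and GC correction their median was -0.13, with 15 lower and 4 higher. Among 31 antioxidant genes 15 were lower and 3 higher, including Prdx5 (-0.91 ± 0.06) and Gsta4 (-0.98 ± 0.07), with camera adjusted p = 0.0141 (adjusted p = 0.556 with an estimated correlation). The length and GC correction ended that list's call, with a median going from -0.24 to -0.05 (adjusted p = 0.127).

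Innate immunity is the second subject of the title. Of 48 tested type I interferon-stimulated genes, 33 were higher, 1 lower and 14 did not pass, with a median log2 fold change of 1.17 (35 higher and 1 lower adjusted over the list alone). The immunity-related GTPase gene Irgm1 went from 585 ± 143 to 11301 ± 3896 normalized counts (4.23 ± 0.29; adjusted p = 0.000183). Its relative Igtp had a log2 fold change of 5.59 ± 0.46, Parp14 of 2.51 ± 0.22, and the RNA-sensing kinase Eif2ak2 of 1.19 ± 0.12. The cytosolic RNA sensors Ddx58 (1.07 ± 0.12) and Ifih1 (1.69 ± 0.21) were higher too. Their list, nucleic acid sensing and inflammasome, had 7 of 25 members higher and 2 lower and missed the threshold (camera adjusted p = 0.0714; adjusted p = 0.67 with an estimated correlation). Of the 10 largest increases with non-overlapping arms, 4 were GTPase genes of this kind or their close relatives, and their reads may be shared between near-identical copies, so single values are uncertain: Gm4841 (29.8 ± 34.7 and 23760 ± 8527), Gm12185 (25.8 ± 12.7 and 10197 ± 5915), F830016B08Rik (299 ± 241 and 65823 ± 18802) and Gm12250 (120 ± 77.8 and 8258 ± 2924). The interferon list had camera adjusted p = 1.17e-09 (adjusted p = 0.556 with an estimated correlation).

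Genes of MHC class I antigen presentation moved with them: 17 of 21 were higher and none lower (18 and 0 adjusted over the list alone), including the peptide transporter Tap1 (2.67 ± 0.31), the peptide trimmer Erap1 (1.33 ± 0.10) and the class I transactivator Nlrc5 (2.99 ± 0.46). Camera gave adjusted p = 2.18e-07 (adjusted p = 0.556 with an estimated correlation). Of 30 inflammatory cytokine and adhesion genes, 13 were higher and none lower (camera adjusted p = 0.000722; adjusted p = 0.556 with an estimated correlation), including the chemokine Ccl8 (2.91 ± 0.51). The complement list missed the threshold (camera adjusted p = 0.0714) with 9 of 19 members higher and 2 lower, and its members C3 (3309 ± 151 and 41051 ± 11677) and C4b (2.06 ± 0.26) were higher. The acute-phase gene Saa3 was higher in every heart (7.01 ± 0.79), as were Chi3l3 (6.48 ± 0.56), Apol9a (6.70 ± 0.57) and Apol11b (6.24 ± 0.67), the last 3 near 0 in the vehicle hearts. Saa1 and Saa2 reached 3943 and 4956 in trametinib replicate 3 and at most 114 and 103 in the other 2 trametinib hearts. Their calls were lost without vehicle replicate 2, and that of Saa2 also without vehicle replicate 1 (adjusted p = 0.0562 to 0.0654). With voom on estimated reads none of Saa1, Saa2 and Saa3 passed, at adjusted p = 0.463, 0.492 and 0.124.

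**Figure D3:**
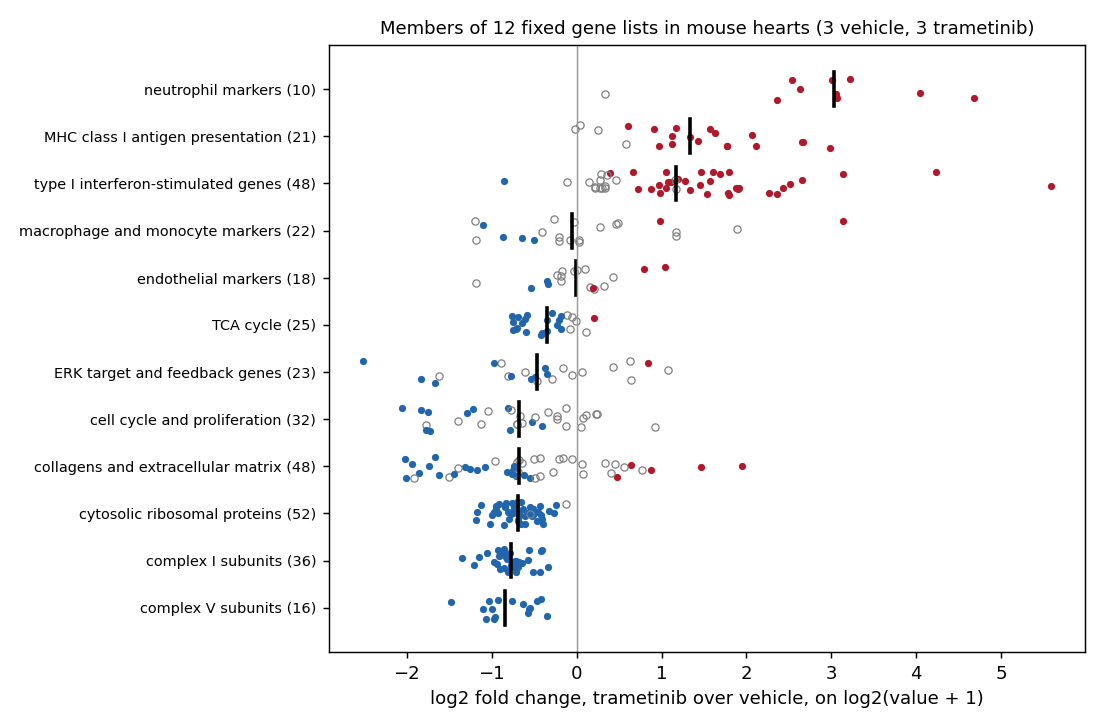
Log2 fold change of trametinib over vehicle (horizontal axis) for each tested member of 12 gene lists (vertical axis, with the number tested), filled where the adjusted p was below 0.05 (red higher, blue lower), open otherwise, with a black line at the list's median. Medians run from 3.03 for neutrophil markers and 1.17 for interferon-stimulated genes to -0.77 for complex I and -0.85 for complex V.

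Of the lists of blood-borne cells, the neutrophil and erythroid lists passed as sets. Of 10 neutrophil markers 9 were higher and none lower, with a median of 3.03, including S100a8 (93.3 ± 71.4 and 660 ± 225), S100a9 (141 ± 100 and 976 ± 385), the collagenase Mmp8 (4.68 ± 0.59) and the chemokine receptor Cxcr2 (3.22 ± 0.48). Ngp had 4.04 ± 0.67 and missed the threshold with voom (adjusted p = 0.0589). Of 6 erythroid markers 5 were higher, including the band 3 anion exchanger Slc4a1 (4.93 ± 0.52), the haem synthesis enzyme Alas2 (306 ± 21.1 and 2783 ± 1778) and Hba-a2 (1.91 ± 0.37). Camera adjusted p was 0.00042 for neutrophil and 0.00194 for erythroid markers, each with adjusted p = 0.556 with an estimated correlation. Macrophage and monocyte markers did not move as a set (camera adjusted p = 0.642): 2 of 22 were higher, including Plac8 (3.14 ± 0.58), and 4 lower, including Lyz2 (-0.65 ± 0.07) and Csf1r (-0.51 ± 0.11). T and NK cell markers had 3 of 10 higher (camera adjusted p = 0.12), and endothelial markers 3 higher and 3 lower of 18 (camera adjusted p = 0.941).

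Nppa, which encodes atrial natriuretic peptide, fell from 4347 ± 1705 to 446 ± 258 normalized counts (log2 fold change -3.36 ± 0.40; adjusted p = 0.00068), and Nppb, which encodes the B-type peptide, measured 3625 ± 974 and 2660 ± 751 (adjusted p = 0.197). Skeletal actin, Acta1, was lower (-2.63 ± 0.43; adjusted p = 0.00236). The atrial genes Myl4 (-2.80 ± 0.85), Sln (-3.59 ± 0.89) and Myl7 (-2.57, chosen after its values were seen) were lower on average, but trametinib replicate 1 had 1467 of Myl4 against 163 and 122 in the other 2, where vehicle hearts had 1573 to 2724. The Myl4 and Myl7 calls were lost without any 1 of 5 hearts, with adjusted p up to 0.0966 for Myl4 and 0.139 for Myl7. They were also lost after the length and GC correction (-2.23 and -1.83, adjusted p = 0.0815 and 0.151). As a set, the atrial and conduction markers did not pass (4 higher and 6 lower of 13; camera adjusted p = 0.562).

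Both myosin heavy chains were higher, Myh6 at 0.47 ± 0.09 (adjusted p = 0.00496) and Myh7 at 0.63 ± 0.07 (adjusted p = 0.000624). The Myh6 call was lost without a filter (adjusted p = 0.0587) and with quantile normalization, which set its change to 0 because it held the highest value in every library. Among 25 sarcomere and Z-disc genes 14 were lower and 8 higher (camera adjusted p = 0.308). The short transcripts Myl3 (-1.02 ± 0.09) and Tcap (-1.60 ± 0.15) were among those lower. Ryr2, the calcium release channel, had 1.00 ± 0.10 and the stress-responsive Xirp2 1.07 ± 0.09. Of 15 ventricular cardiomyocyte markers 11 were lower and 2 higher, with myoglobin, Mb, at -0.96 ± 0.09 (camera adjusted p = 0.0102; adjusted p = 0.556 with an estimated correlation). The length and GC correction ended this list's call, taking its median from -0.45 to -0.09 (adjusted p = 0.564), as did quantile normalization (adjusted p = 0.0504) and the 4 members of no other list (median -0.13, adjusted p = 0.416). The correction also reduced the changes of Ryr2 (to 0.52), Xirp2 (to 0.48) and Myl3 (to -0.39).

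Of 48 collagens and extracellular matrix genes, 19 were lower, 5 higher and 24 did not pass, with Lum at -1.31 ± 0.11, the microfibril gene Mfap5 at -2.00 ± 0.25 and Col15a1 at -1.85 ± 0.20 (camera adjusted p = 0.00898; adjusted p = 0.688 with an estimated correlation). The call was lost with fry (adjusted p = 0.143) and without trametinib replicate 2 (adjusted p = 0.0769), where 13 were lower and 9 higher and the median went from -0.68 to -0.39. Without vehicle replicate 1, 27 were lower and 2 higher. Of 14 fibroblast markers 8 were lower, such as Gsn (-1.26 ± 0.11), and 2 higher, such as Ddr2 (0.58 ± 0.08; 0.26 after the length and GC correction, adjusted p = 0.053). The fibroblast list had camera adjusted p = 0.0322 (adjusted p = 0.582 with an estimated correlation), a call lost without vehicle replicate 2 (adjusted p = 0.0633) or trametinib replicate 2 (adjusted p = 0.0601). It was also lost with the 8 members of no other list, where the median was -0.38 (adjusted p = 0.337) against -0.74. Of 32 cell cycle genes 11 were lower (7 without vehicle replicate 3), none higher and 21 did not pass (9 lower adjusted over the list alone), including Cenpa (-1.84 ± 0.18), Ccna2 (-1.72 ± 0.23), Cdk1 (-2.05 ± 0.41) and Top2a (-1.77 ± 0.35; camera adjusted p = 0.00597; adjusted p = 0.556 with an estimated correlation).

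Among the largest decreases outside the lists, the eotaxin Ccl24 went from 75.65 ± 18.96 to 1.52 ± 0.54 normalized counts (-4.92 ± 0.39; adjusted p = 0.000269), Cytl1 had -2.77 ± 0.44 and the Wnt inhibitor Wif1 -2.60 ± 0.45. Hist1h2ag (-3.63 ± 0.90) and 1500015O10Rik (-3.78 ± 1.16) lost their calls without vehicle replicate 2, at adjusted p = 0.0524 and 0.0822, and 1500015O10Rik also without vehicle replicate 3 (0.1). The call of 1500015O10Rik was also lost with the replicate block and after the length and GC correction.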

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

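Median-of-ratios scaling, the length and GC correction, voom on estimated reads and thinning were chosen after seeing the data. The planned count tests (2 tools) and their upper-quartile and size-factor versions were not run, because the values were not counts; quantile normalization and limma without trend took their place. The 6037 changed genes became 4667 to 5576 with a heart left out (lowest without trametinib replicate 1 or 3), 5849 after thinning and 6103 with voom. The length and GC correction gave 4499, of which 3462 were among the 6037. Requiring a log2 fold change of 1 left 805 genes, 388 higher and 417 lower, by construction. With the replicate number as a block, 5762 genes passed. In deviations from the arm means, 1 of the 3 vehicle hearts correlated best with the trametinib heart of its own number (same-number r of 0.24, 0.02 and 0.50). The second principal component, with 20.6% of the variance, set replicate 3 of both arms (-34.4 and -28.8) apart from the other hearts. Whether hearts of the same number shared a batch therefore stays open, and the labels give only the number. With the block, Dusp6 (adjusted p = 0.00561) and Ppargc1a (0.00635) passed, and 1500015O10Rik lost its call.

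Of 44 lists, 18 passed with camera, 18 to 21 with a heart left out, 20 with the block, 25 with fry and 0 with an estimated correlation, where complex I (median -0.77) and the interferon list (1.17) had adjusted p = 0.556; with 6 libraries those correlations rest on few values. The ERK target list, at a median of -0.47, passed with fry (adjusted p = 0.0425) and the block (0.0467) at the same median, without a filter at -0.42 (0.0461) and after the length and GC correction at -0.57 (0.0115). With a heart left out its median ran from -0.51 to -0.36 and its adjusted p from 0.0297 to 0.163.

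The length and GC correction reversed Map2k2 (0.22, adjusted p = 0.0131) and Mapk3 (0.10, adjusted p = 0.186); the cause was not tested. Over all alternatives, 1885 values of the 109 named genes kept direction and side of the threshold, 51 lost the call and 6 gained it. The first component held 58.4% of the variance over the 500 most variable genes, against 57.2%. The vehicle hearts' lower depth limits what can be said of genes near 0 there.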

Other observations

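Circadian transcripts went both ways. Dbp, an output gene of the clock, fell from 2364 ± 1275 to 365 ± 173 normalized counts (adjusted p = 0.00182), Gm129 had a log2 fold change of -2.32 ± 0.34 and Per3 of -1.18 ± 0.24, while Clock (1.02 ± 0.10) and Nfil3 (380 ± 123 and 1075 ± 131) were higher. The list had 5 higher and 7 lower of 18 (camera adjusted p = 0.455), with 3 higher without trametinib replicate 1 or 3. Camera looks for a shift in a shared direction and would miss opposite shifts. The hour of collection is not given in the sources used here. A difference in that hour between the arms therefore cannot be told apart from an effect of treatment. Groups formed after the values were seen included 75 mitochondrial ribosomal protein genes, 67 of them lower and none higher (median -0.51), and 20 import subunits of the Tomm and Timm families, 19 lower and 1 higher (median -0.55). After the length and GC correction 34 of the first group were lower and 6 higher (median -0.18), and 12 of the second were lower and none higher (median -0.30). Of 37 proteasome subunits outside the MHC class I list 23 were lower and 2 higher (median -0.23), and of 18 histone genes 8 were lower and none higher (median -0.25). Both calls ended with the correction, at medians of -0.02 (adjusted p = 0.744) and -0.14 (adjusted p = 0.307). All 21 interferon-inducible GTPases were higher, with a median of 3.74, and 20 were after the correction (median 3.65). With an estimated correlation the adjusted p of these 5 groups ran from 0.125 to 0.253. In the smooth muscle and pericyte list, Rgs5 (0.68 ± 0.06) and Myh11 (1.34 ± 0.24) were higher, and as a set the list did not pass (6 higher and 1 lower of 13; median 0.17; camera adjusted p = 0.332).

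The tests on cell types, neutrophils and atrial tissue below were chosen after the results were seen. The real split of the 6 hearts gave 6037 changed genes and the highest of the other 9 splits gave 0; with 10 splits in all, 1 of them the real one, no share can fall under 0.1.

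The respiratory chain and ribosomal protein transcripts were lower with trametinib. Length and GC content as the whole cause were tested with matched lists. The subunits lay 0.32 below the median of theirs (-0.319 on the log2 scale, range -0.27 to -0.35 over 4 ways of matching). The ribosomal proteins lay 0.20 below (-0.196, range -0.16 to -0.23). Lengths were plain means over each gene's annotated transcripts, whichever were expressed, so matching can leave part of a length effect. The draws also took genes independently, whereas subunits varied together (estimated correlation 0.87 in complex I). The test therefore cannot exclude length and GC content as the whole cause. The matched lists themselves had medians of -0.46 and -0.49, so most of each decrease was shared with other transcripts of like length, GC content and level. Thinning left the subunits' median at -0.82 against -0.78. Ratios of transcripts at such high counts hardly move when reads are removed, so thinning was no real test of depth. It also cannot reach library differences that go with depth. A smaller share of cardiomyocyte RNA as the whole cause would raise the markers of the other resident types alike. Fibroblast markers had a median of -0.74, and the pooled endothelial, mural and macrophage markers -0.03 (permutation p = 0.00154), and the difference of -0.71 was -0.84 after the length and GC correction (permutation p = 0.00043). It was -0.36 with the 8 fibroblast markers of no other list (permutation p = 0.19), and genes are not independent replicates in these permutations. A treatment effect on fibroblast genes would give the same difference, so the test cannot decide on the cardiomyocyte share. The pooled endothelial, mural and macrophage markers, at -0.03, showed no rise as a group before the length and GC correction. After it their median was 0.12, so the absence of a rise depends on the version. The pooled test followed a first one against mural markers alone, where the difference was -0.90 (permutation p = 0.0146), or -0.77 without the mural list's one gene that a muscle list also holds (permutation p = 0.0559). For the decrease, most of which was shared with transcripts of like length, a treatment effect and an RNA quality difference that follows length both stay open.

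Interferon-stimulated transcripts were higher with trametinib. A general rise in macrophages and monocytes was argued against as the source. The bootstrap 95% interval of their markers' median, drawn over genes and not animals, ended at 0.38, below the interferon list's 1.17. Of these 22 markers 2 were higher, such as Plac8 (3.14), and 4 lower, such as Lyz2 (-0.65). Whether such cells changed in kind or state was not tested. More neutrophils cannot be told apart: 9 of 10 neutrophil markers were higher, and of the 33 interferon-stimulated transcripts that were higher, 8 gained more normalized counts than the abundant neutrophil transcript S100a9, which gained 835, and the other 25 gained less. The bound first set, at least 5 transcripts, was too weak, because it rests on the largest gains alone and leaves most of the list untested, so a majority of the higher members was required instead, after the values were known. Matching on length and GC content left a difference of 1.17 from the matched lists. Reads shared between GTPase copies and an infection or batch that followed the arms were not tested.

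Nppa was lower with trametinib. If the trametinib samples had held less atrial tissue, the Nppa to Myl7 ratio would have stayed in the vehicle range of 1.76 to 3.79. It lay below that range in 1 of the 3 trametinib hearts (0.589 in replicate 1) and inside it in the others (2.29 and 3.17). Less atrial tissue and a lower Nppa level in the tissue cannot be told apart with these 3 hearts.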
